A study of Mus musculus with 4 samples.

How the data were processed

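Lungs of 4 tumor-bearing mice were imaged by Xenium, an in situ method that counts transcripts of a targeted gene panel within segmented cells of a tissue section. Per the labels, 2 mice carried B16F10 melanoma and 2 carried KPAR1.3 adenocarcinoma, and the lungs were perfused and inflated with 10% neutral buffered formalin and fixed for 12 h. Each deposited matrix holds raw transcript counts per feature and cell, per the file headers and the whole-number values. Segmentation, the quality threshold behind each count and the software version are not given in the sources used here. The files used here held no cell coordinates, images or cell annotation, so distances between cells were not analysed here.

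Every matrix listed 541 features. The labels name a 100-gene panel for all 4 samples, but the B16F10 matrices and panel designs hold 300 genes and those of KPAR1.3 hold 100. Symbols and Ensembl gene IDs, as paired in the deposited feature lists, were shared by 96 genes, and all comparisons between models used these 96 alone. Panel and tumor model are therefore confounded. Of the shared genes, 3 (Ccl4, Isg15 and Ly6c2) had another number of probe sets in the 2 panels. All 304 symbols of either panel were found in a reference gene table (assembly GRCm38.p6), which held none of the Ensembl IDs. It was used for names only.

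Cells with at least 10 transcripts of the shared genes were kept. Counts were scaled to the median total and log-transformed for 15000 cells drawn per section, then reduced to 20 principal components and joined by 15 nearest neighbours. Leiden clustering at resolution 1 over the 40 shared genes from fixed cell type marker lists gave 53 clusters. All kept cells were then assigned to the cluster whose mean profile gave the highest multinomial likelihood; 73.4% of the drawn cells were assigned back to their own cluster. A cluster was named where its 10 genes with the largest fold over all other cells held at least 3 markers of 1 class and that class led. After the data had been examined, a cluster also lost its name where Pmel, a melanoma gene, exceeded 25% of the highest cluster, or where Ptprc, the leukocyte gene CD45, was under 50% of the leukocyte median. Pmel was in the B16F10 panel and not in the KPAR1.3 panel, so that check rested on B16F10 cells alone. By the Pmel check, a non-alveolar-named and a monocyte-named cluster lost their names. The non-alveolar-named cluster held 1.95% and 1.02% of kept B16F10 cells and 0.395% and 0.294% of kept KPAR1.3 cells. The monocyte-named cluster held 0.298% and 0.266% of kept B16F10 cells and 8.08% and 3.20% of kept KPAR1.3 cells. Its Pmel per cell was 23.2 and 5.53 in B16F10 replicates 1 and 2, and only replicate 1 exceeded the limit. One class each of alveolar macrophage-like, non-alveolar macrophage-like and dendritic cell-like cells was named. Monocyte-derived and interstitial macrophages could not be separated with this panel, so neither is named, and the classes are not called recruited or resident. Software was Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and leidenalg 0.10.2, and matplotlib 3.10.9 drew the plots.

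The mouse was the replicate. Counts were summed per mouse over all kept cells or over the cells of a class, and tested with edgeR 4.0.16 (R 4.3.3): TMM scaling on the total over the shared genes, the quasi-likelihood test, and Benjamini-Hochberg adjustment over the genes tested with a threshold of 0.05. Between models, a gene needed a mean count of 100 per section, or 20 per macrophage class, in at least 1 model. It also needed a count above the mean negative control probe, and all 96 genes met this. Fits that contrast the 2 macrophage classes needed a mean count of 20 in at least 1 class, without a check against control probes. The models were compared without a block, since the replicate numbers only name mice. Alveolar and non-alveolar classes come from the same mice, so mouse was a term in that fit, which was run on the 56 shared genes that took no part in clustering. A class-by-model term tested whether the class contrast differed between models. Shares of kept cells were tested with edgeR on cell numbers, with the kept cells as library size and 1 dispersion for the 3 classes, a form chosen after the data had been examined, and with an exact two-sided permutation test, whose smallest p for 2 against 2 is 0.333. Shares of ligand transcripts per class are given without a test, and their median over 10 ligands was chosen afterwards as their summary.

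Gene lists (chemokine ligands, chemokine receptors, interferon-gamma-inducible genes, a tumor-promoting macrophage program, inflammatory cytokines, antigen presentation, scavenging and lipid handling, and T cell function) were fixed before the data were examined. Lists with at least 5 tested members were tested with camera in limma 3.58.1, at a preset inter-gene correlation of 0.01 and at an estimated one. No member of the T cell list was in both panels, so it was not analysed here. Named genes followed a rule fixed beforehand: per comparison up to 10 genes with the largest positive and up to 10 with the largest negative log2 fold change among those that passed without overlap between the mice compared, every chemokine ligand in the macrophage comparisons, and up to 4 members of each other list with the highest counts. Not every gene that the rule picks is printed. Sources were described for the 10 ligands with the highest counts and at least 100 counts per section. A few markers of other cell types are named outside this rule, and where they are the text says so.

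The alternatives tried were the total count without TMM, an offset by cell number, DESeq2 1.42.0, no filter on low counts, 5 or 20 transcripts per cell, each mouse left out in turn, the replicate number as a block or no mouse term, Leiden resolution 2, clusters made per model, a marker gate in place of clusters, and, chosen after the data had been examined, the clusters that lost their name put back. Of the clusters put back, only the non-alveolar-named one joins a class compared here, and the monocyte-named one joins none. For shares, TMM over classes and immune-named cells as the denominator were also tried. The immune-named cells were those of the 3 named classes alone. The gene tests were run on simulated data, with 20 sets for each comparison except the class-by-model term, which was not simulated. In each set 20 genes were changed, a number set by the small panel. At a true fold of 4, 90.3% of changed genes were called for whole sections, 96.2% for non-alveolar and 92.3% for alveolar cells between models, and 100% between classes. At a fold of 2 the shares were 33.6%, 38.3%, 46.2% and 66.7%, and at 1.5 they were 11.8%, 8.21%, 14.3% and 31.2%, so small changes between models were mostly not detectable with 2 mice per model. Among calls, 4.04%, 3.55%, 4.76% and 2.67% were of unchanged genes. The simulated changes went up and down in equal numbers, so these shares do not cover errors that come from scaling.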

Results

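Transcripts were counted in situ in lung sections of 2 mice with B16F10 tumors, a mouse melanoma line, and 2 mice with KPAR1.3 tumors, a mouse lung adenocarcinoma line. The B16F10 sections held 426641 and 517413 segmented cells and the KPAR1.3 sections 876258 and 678432. Transcripts of the 96 genes in both panels totalled 35865372 and 35744651 in B16F10 and 105447349 and 63128976 in KPAR1.3, with medians of 64, 55, 89 and 71 per cell. Over all panel genes the totals were 120196427 and 114202837 for the 300-gene panel and 113094042 and 66795565 for the 100-gene panel. A negative control probe drew on average 121 and 175 counts per B16F10 section and 471 and 321 per KPAR1.3 section, and the highest of 20 probes drew 574 and 932 and, in KPAR1.3, 6236 and 4608. Of all cells, 98.7% to 99.3% were kept. At these totals counting error was small against the differences between mice: chi-square per degree of freedom between replicates was 13412.8 for B16F10 and 45863.4 for KPAR1.3.

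The first question was which macrophage-like and dendritic cell-like cells the sections held, since the series contrasts recruited and resident tumor-associated macrophages. The alveolar macrophage-like class, led by Chil3, Siglecf and Ear1, made up 4.90% ± 0.00094 of kept B16F10 cells and 3.74% ± 0.745 of kept KPAR1.3 cells (SD, n = 2 each). Non-alveolar macrophage-like cells, led by Cd163, Folr2 and the complement genes C1qc and C1qb, were assigned 3.32% ± 0.123 and 9.47% ± 1.47. Dendritic cell-like cells, led by Clec9a, Xcr1 and Cd209a, were assigned 1.56% ± 0.361 and 4.09% ± 0.623. Cd163 and Itgax, which helped to define these classes, themselves differed between models, so these are shares of assignments and not measures of abundance.

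In edgeR, the assigned share was lower in B16F10 by a log2 fold change of -1.51 ± 0.23 (SE) for non-alveolar macrophage-like cells (adjusted p = 0.0013) and of -1.39 ± 0.23 for dendritic cell-like cells (adjusted p = 0.0013). Alveolar macrophage-like cells did not pass at 0.39 ± 0.22 (adjusted p = 0.132). The exact two-sided permutation test gave p = 0.333 for each class, the smallest it can give with 2 mice per model. These shares leave out the non-alveolar-named cluster that lost its name by the Pmel check. It held 1.95% and 1.02% of kept B16F10 cells and 0.395% and 0.294% of kept KPAR1.3 cells. Leaving it out thus widened the non-alveolar difference. The non-alveolar call ended with the marker gate (-0.42, adjusted p = 0.235) and without B16F10 replicate 1 (-1.47, adjusted p = 0.0523). The dendritic call ended without B16F10 replicate 1 (-1.17), KPAR1.3 replicate 1 (-1.23) or KPAR1.3 replicate 2 (-1.54), and the alveolar share passed among immune-named cells (1.20, adjusted p = 0.0057) and without KPAR1.3 replicate 1 (0.20) or KPAR1.3 replicate 2 (0.61).

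**Figure D1:**
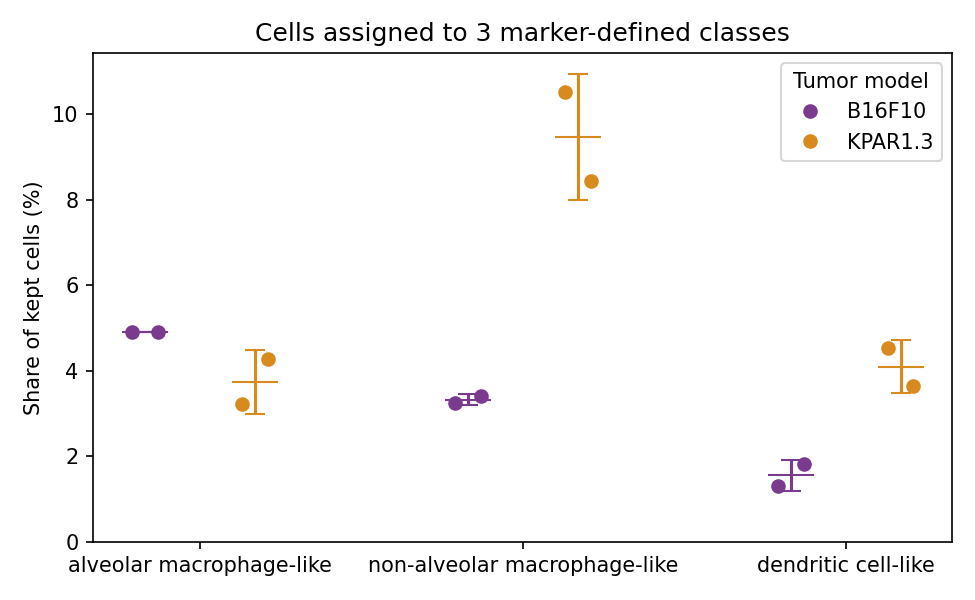
Share of kept cells (%) assigned to each of 3 classes, with 1 point per mouse and the mean and SD of 2 mice per tumor model. Non-alveolar macrophage-like cells took 3.24% and 3.41% of the B16F10 sections and 10.5% and 8.43% of the KPAR1.3 sections.

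Whole sections were compared next, to show how the tumor-bearing lungs of both models differed before cells were parted. Irf1, a transcription factor induced by interferons, had the largest difference: it was at 1.41 ± 0.22 per 1000 shared-gene transcripts after TMM scaling in B16F10 and 12.2 ± 2.46 in KPAR1.3 (SD, n = 2 each), a log2 fold change of -3.11 ± 0.35 (SE, adjusted p = 0.00033). Chemokines fell with it in B16F10 lungs. Cxcl9, which attracts T cells through Cxcr3, lay at -2.38, Ccl8 at -2.28, Ccl17 at -2.16 and Ccl22 at -1.70. Ccl22 stood at 1.21 and 1.16 per 1000 in B16F10 and at 5.96 and 1.77 in KPAR1.3 replicates 1 and 2. Its fall thus rests in large part on KPAR1.3 replicate 1. A cluster led by Cd3e, Ccr7 and Ccl22 held 16.2% of kept cells in that mouse and 3.08% in KPAR1.3 replicate 2. Acta2, a smooth muscle and fibroblast actin, rose in B16F10 lungs by 1.82 ± 0.25 and the endothelial gene Pecam1 by 1.34 ± 0.27. Acta2, like Ctsd, Bhlhe40 and Fabp5 named below, was among the 10 leading genes of the melanoma-rich cluster, which had the most Pmel. That cluster held 9.17% and 3.25% of kept B16F10 cells and 0.318% and 0.407% of kept KPAR1.3 cells. How much of these rises came from tumor cells was not tested. Ifit1, which interferons also induce, rose by 1.03 ± 0.34 (adjusted p = 0.032, chosen after its value was seen).

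Of 96 genes, 35 passed edgeR's quasi-likelihood test, 18 higher and 17 lower in B16F10, and in all 35 the mice of the 2 models were apart without overlap, as chance alone gives for 33.3% of genes and the test favors. Pdpn (1.85), Car4 (1.68) and Pdgfra (1.27) also rose. Retnla (1.74), Cd163 (1.31), Chil3 (1.19), Bhlhe40 (1.35) and the lysosomal protease gene Ctsd (1.31) rose as well. Itgax, which encodes CD11c, fell by 1.88 on the log2 scale, the lectin gene Clec4n by 1.83, Il4i1 by 1.93, the T cell gene Cd3e by 1.76 and Itgae by 1.57. Cd3e stood at 2.07 and 1.92 per 1000 in B16F10 and at 10.8 and 2.71 in KPAR1.3 replicates 1 and 2. In the same KPAR1.3 mice Il4i1 stood at 3.78 and 1.36 and Itgae at 3.703 and 1.505. The fall of Cd3e thus rests in large part on KPAR1.3 replicate 1, and those of Il4i1 and Itgae rest on it in part. Cd3e, Il4i1 and Itgae were among the leading genes of the cluster described with Ccl22 above.

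By list, 0 of 20 chemokine ligands rose, 5 fell and 15 did not pass in whole sections (5 when adjusted over the list alone). Camera placed the ligands below the other genes (adjusted p = 0.0079), and this was lost at adjusted p = 0.509 with an estimated correlation. Of 4 interferon-gamma-inducible genes, Irf1 and Cxcl9 fell and 2 did not pass, with Cxcl10 at -0.91 and Nos2 at -0.80 (2 passed when adjusted over the list alone). Of 7 tumor-promoting genes, Cd163 and Chil3 rose and 5 did not pass, with Fn1 at 0.24, Mrc1 at 0.26 and Mmp12 at -0.98 (2 adjusted over the list alone). Ccr2, the receptor of monocyte-attracting chemokines, fell by 1.09 and was the only one of 5 receptors to pass (1 adjusted over the list alone), with Ccr7 at -0.53, Cxcr3 at -0.81 and Cx3cr1 at -0.66. Fabp5 rose by 1.16 and was the only one of 3 scavenging and lipid genes to pass, with Apoe at -0.67 and Timd4 at -0.61 (1 adjusted over the list alone). Neither antigen presentation gene passed over all genes, with H2-Aa at -0.16 and H2-Ab1 at -0.67 (1 adjusted over the list alone), nor did Il1b at -0.15.

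The median log2 fold change over the 96 genes in whole sections was -0.27, and it moved to -0.74 with the total count in place of TMM (8 genes higher and 39 lower) and to -1.25 per cell (1 higher and 45 lower), so the balance of higher and lower genes rests on the scaling. Without B16F10 replicate 1 the test called 14 genes and without B16F10 replicate 2 it called 12.

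In non-alveolar macrophage-like cells the comparison asked how this class differed between the models. The interferon-gamma-inducible genes fell together in B16F10: Irf1 lay at -3.71 ± 0.26, Cxcl9 at -2.06 ± 0.37, Cxcl10 at -1.74 ± 0.31 and Nos2, the inducible nitric oxide synthase, at -1.08 ± 0.29 (log2 fold change, SE). Irf1 stood at 0.570 ± 0.059 per 1000 in B16F10 and 7.45 ± 1.12 in KPAR1.3 (SD, n = 2 each). Cd163, a hemoglobin scavenger receptor, rose by 2.62 ± 0.32, from 3.60 ± 1.49 per 1000 in KPAR1.3 to 22.1 ± 0.019 in B16F10. The mannose receptor gene Mrc1 rose by 1.04 ± 0.14 and the growth factor gene Igf1 by 1.43 ± 0.23. The make-up of this class differed as well: of its B16F10 cells, 64.7% and 69.3% lay in a cluster led by Cd163 when clusters were made per model, and 5.54% and 1.70% in a cluster with Mmp12 among its leading genes. Of its KPAR1.3 cells, 10.4% and 19.9% lay in a cluster led by Cd163, 54.8% and 46.6% in one led by Mmp12 and 15.2% and 15.4% in one led by Nos2. This make-up depends in part on the Pmel check. That check took out a non-alveolar-named cluster with Mmp12 among its leading genes, of 8241 and 5213 B16F10 and 3434 and 1966 KPAR1.3 cells.

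Of 96 genes, 46 passed in non-alveolar cells, 22 higher and 24 lower in B16F10, and 25 of them took no part in clustering. All 46 were without overlap between the models, as chance alone gives for 33.3% of genes. The adjusted p was 0.000446 for Irf1 and 0.00208 for Cd163. Itgax fell by 2.50, Clec4n by 2.57 and Il4i1 by 1.80 on the log2 scale, whereas Flt3 rose by 1.58, Siglech by 1.43 and the macrophage gene Adgre1 by 1.18. Relative to the median gene of each cluster, Igf1 (median log2 ratio 1.44) and Pf4 (1.24) were higher and Clec4n (-1.45) lower in B16F10 in all 49 clusters with at least 500 cells per section, so these changes were not particular to this class. The cystine transporter gene Slc7a11 fell by 1.34 but lay at 0.31 with the marker gate. Markers of other cell types moved within this class too: Acta2 rose by 1.19, Pdgfra by 1.17 and Pecam1 by 0.88, whereas Cd3e fell by 1.304 and the monocyte genes Ly6c2 and Plac8 by 1.05 and 0.83 (Pecam1, Ly6c2 and Plac8 were chosen after their values were seen).

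Chemokine ligands went both ways in non-alveolar cells, with 3 of 20 higher in B16F10, 10 lower and 7 not passed (14 when adjusted over the list alone). Those that fell were Ccl17 (-2.27), Cxcl9, Cxcl10, Ccl8 (-1.31), Ccl22 (-1.20), Ccl3 (-1.19), Ccl4 (-0.96), Cxcl16 (-0.69) and the monocyte attractants Ccl2 (-1.12) and Ccl7 (-0.92). Pf4, the gene of platelet factor 4, rose by 1.51 and Ccl24 by 1.27, and Ccl9 rose by 0.62 but was at -0.20 per cell and -0.067 with the marker gate. The 7 others were Cxcl2 at 1.06, Cxcl13 at 0.86, Cxcl14 at 0.33, Ccl6 at -0.16, Ccl12 at -0.19, Cxcl3 at -0.65 and Ccl5 at -0.81. Camera did not separate the ligands from other genes (adjusted p = 0.0913, and adjusted p = 0.268 with an estimated correlation).

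Of 7 tumor-promoting genes in non-alveolar cells, Cd163, Mmp9 (1.62), Mrc1 and Fn1 (0.38) rose and 3 did not pass (4 adjusted over the list alone). Fn1 was at -0.44 per cell and -0.029 with the marker gate. All 4 genes that rose took part in clustering, and Cd163 and Mrc1 are among the markers that name this class. The held-out members, Arg1 at 0.45 and Mmp12 at -0.24, did not pass. The list result, camera's included, therefore rests on genes that helped to define the cells. Camera placed this list above the other genes (adjusted p = 0.0495), which was lost at adjusted p = 0.268 with an estimated correlation. All 4 interferon-gamma-inducible genes fell, also when adjusted over the list alone. Among antigen presentation genes, H2-Aa rose by 0.27 but was at -0.56 per cell and -0.43 with the marker gate, and H2-Ab1 fell by 0.33 (2 adjusted over the list alone). Timd4, a receptor for dying cells, rose by 1.08 but lay at -0.27 with the marker gate, Apoe fell by 0.61 and Fabp5 did not pass at -0.35 but rose by 1.01 with the gate (2 adjusted over the list alone). Cxcr3 fell by 0.86 and the other 4 receptors did not pass (0 adjusted over the list alone), with Ccr2 at -0.29, Ccr7 at -0.67 and Cx3cr1 at 0.27, and Il1b did not pass at -0.68.

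Without B16F10 replicate 2, edgeR called 0 of 96 genes in non-alveolar cells (37 at an unadjusted p under 0.05), with the remaining B16F10 mouse assumed to vary like the others, and the marker gate called 30. The median log2 fold change of -0.04 moved to -0.28 with the total count and to -0.86 per cell, where 1 gene was higher and 46 lower.

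**Figure D2:**
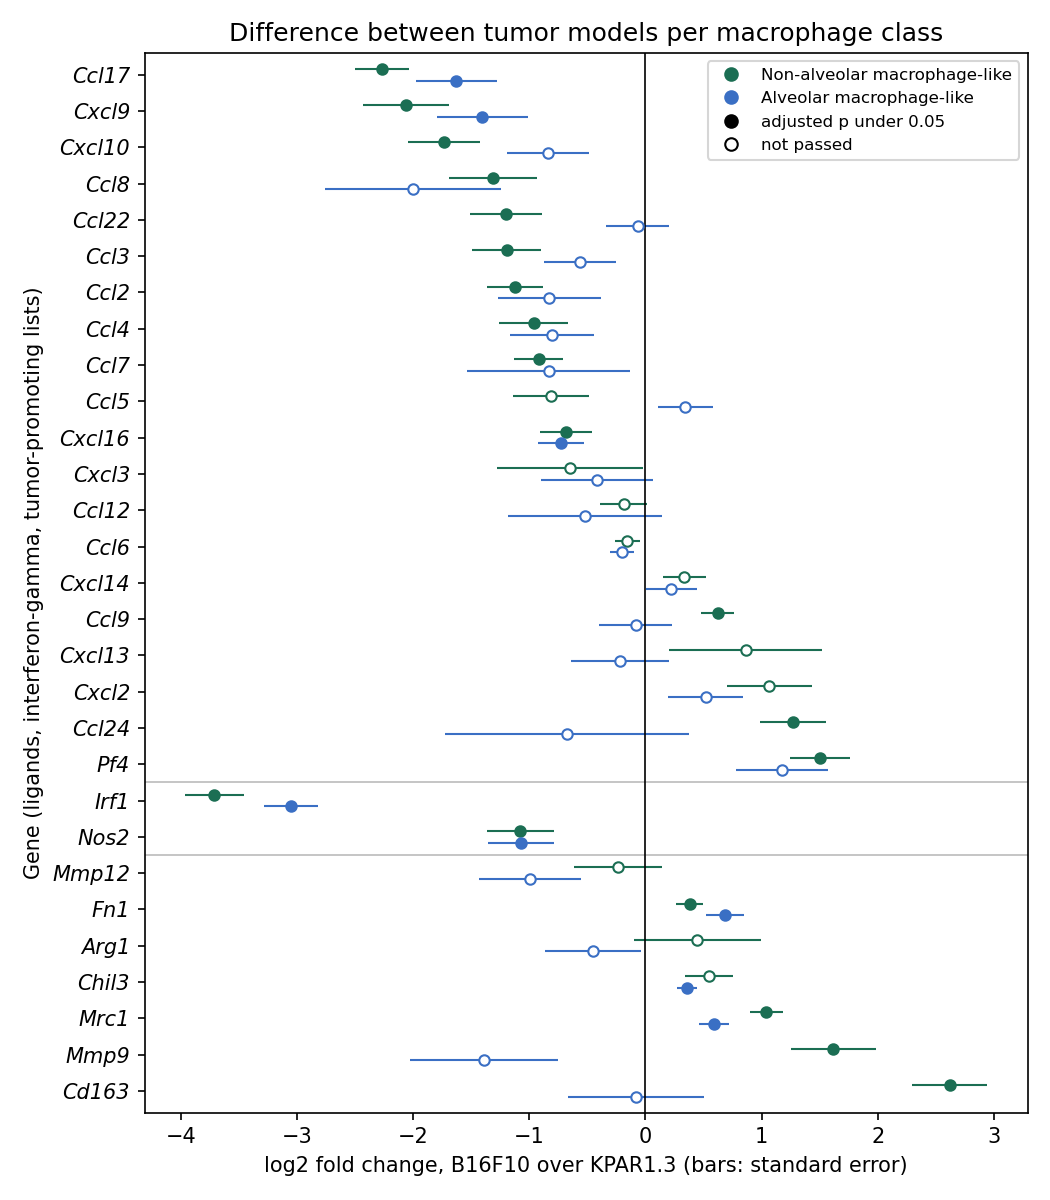
Log2 fold change (B16F10 over KPAR1.3) with its standard error for chemokine ligands, interferon-gamma-inducible genes and tumor-promoting genes in 2 macrophage-like classes, with filled points where the adjusted p was under 0.05. Irf1 lay at -3.71 and -3.05 and Ccl17 at -2.27 and -1.63 in non-alveolar and alveolar cells; per cell, Ccl9 and Fn1 in non-alveolar cells and Chil3 in alveolar cells turned negative.

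Alveolar macrophage-like cells, the macrophages of the air spaces, were compared between models in the same way. Irf1 again fell furthest in B16F10, with a log2 fold change of -3.05 ± 0.23 (SE, adjusted p = 0.000327), with Cxcl9 at -1.40 ± 0.39 and Nos2 at -1.07 ± 0.28. The complement receptor gene C5ar1 fell by 0.94 on the log2 scale and Apoe, which carries lipids, by 1.36, though Apoe lay at 0.18 with clusters made per model. In that setting a B16F10 cluster led by Fabp4, without Chil3, Siglecf or Ear1 among its leading genes, joined the class (4152 and 5641 cells, of which 0.0482% and 0.284% lay in the class otherwise). Genes that rose in B16F10 included Osm, which encodes the cytokine oncostatin M (1.46 ± 0.27), Retnla (1.34 ± 0.23), the transcription factor gene Bhlhe40 (1.18 ± 0.19) and Igf1 (1.08 ± 0.25).

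In this class 31 of 96 genes passed, 16 higher and 15 lower, and all 31 were without overlap between the models, as chance alone gives for 33.3% of genes. Itgax fell by 1.22, Clec4n by 1.05 and Mgl2 by 0.99. Of the alveolar macrophage markers Siglecf (0.74) rose and Ear1 did not pass (0.22), and Car4 (0.81), which also led clusters with high Pecam1, rose. Igf1, Bhlhe40, Irf1 and Clec4n moved in these directions in all 49 clusters. Of chemokine ligands, Ccl17 (-1.63), Cxcl9 and Cxcl16 (-0.73) fell, none of the 20 rose and 17 did not pass (1 adjusted over the list alone); camera gave adjusted p = 0.357. The ligands that did not pass ranged from -2.00 for Ccl8 to 1.18 for Pf4, with Cxcl10 at -0.84, Ccl2 at -0.83, Ccl6 at -0.20 and Ccl5 at 0.34. Of the interferon-gamma-inducible genes 3 of 4 fell (4 adjusted over the list alone).

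Among tumor-promoting genes in alveolar cells, Fn1 (0.69), Mrc1 (0.59) and Chil3 (0.36) rose and 4 did not pass (3 adjusted over the list alone). Per cell, Chil3 was at -0.17. All 3 genes that rose took part in clustering, and Chil3 is a marker that names this class. The held-out members, Arg1 and Mmp12 (-0.995), did not pass. The list's median of -0.08 and mean of -0.18 were negative while camera's direction was up (adjusted p = 0.501). H2-Ab1 fell by 0.62 and H2-Aa did not pass at 0.09 (1 adjusted over the list alone). Fabp5 rose by 0.69, Apoe fell and Timd4 did not pass at -0.75 (2 adjusted over the list alone). Ccr2 fell by 1.05 and the other 4 receptors did not pass (0 adjusted over the list alone), with Ccr7 at 0.60, Cxcr3 at -0.48 and Cx3cr1 at -0.37, and Il1b did not pass at 0.08. Markers of other cell types moved here as well: Acta2 rose by 1.27, the epithelial gene Napsa by 0.77 (-0.92 with clusters made per model) and Pecam1 by 0.59 (Pecam1 was chosen after its value was seen). Of the B16F10 cells of this class, 10.3% and 9.89% lay in a cluster with Napsa and Sftpd among its leading genes when clusters were made per model.

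With 1 mouse of the KPAR1.3 arm left out and the remaining one assumed to vary like the others, edgeR called 0 genes in alveolar cells without KPAR1.3 replicate 1 (33 at an unadjusted p under 0.05) and 18 without KPAR1.3 replicate 2. The median log2 fold change of -0.16 moved to -0.41 with the total count and to -0.68 per cell, where 2 genes were higher and 28 lower. Between the macrophage-like classes, 19 genes passed in both, and all 19 had the same sign, 7 higher and 12 lower in B16F10, against 3.67 and 3.75 expected for independent lists; both lists come from the same mice.

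The contrast of alveolar with non-alveolar macrophage-like cells within each mouse asked which of the genes held out of clustering told the classes apart. Alveolar cells were richer in the chemokine Ccl6, by 2.45 ± 0.07 (log2, SE), at 144 ± 14.3 against 26.5 ± 2.93 per 1000 (SD, n = 4), and in the tetraspanin gene Cd9, by 3.05 ± 0.12. They were poorer in most other ligands: Ccl8 lay at -5.20 ± 0.54, Cxcl13, which attracts B cells, at -4.66 ± 0.52, Pf4 at -3.87 ± 0.32 and the monocyte attractant Ccl2 at -3.03 ± 0.27. Arg1 (-1.82), Mmp12 (-2.18), H2-Aa (-1.21) and H2-Ab1 (-1.39) were also lower in alveolar cells. In B16F10 replicate 1, an alveolar cell held 0.0018 counts of Ccl8, and 0.0018 of Timd4 and 0.0010 of Ccl24, named below. A negative control probe drew 0.00039 counts per cell there on average. The sizes of such large falls are therefore uncertain, with Ccl8 at -6.90 and -4.31 in the B16F10 mice.

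Of 56 genes, 46 passed, 23 higher and 23 lower in alveolar cells; Ccl6 had an adjusted p of 2.3e-05 and was higher in 4 of 4 mice. The others that led among higher genes were Clec4n (2.35), Ctsd (2.19), C5ar1 (1.86), Fabp5 (1.65), Stmn1 (1.64), Nes (1.43), Bhlhe40 (1.39) and Wwtr1 (1.25). With the total count Fabp5 (0.67) and Bhlhe40 (0.42) did not pass, whereas the rest of this list did. Ctsd, Fabp5, Stmn1 and Bhlhe40 were also among the leading genes of the melanoma-rich cluster, and a part of melanoma transcripts in their rise was not tested. Lower genes included Timd4 (-4.93), Ccl12 (-4.21), Ccl24 (-4.11), Ccl7 (-3.81) and Retnla (-3.02).

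Of 20 chemokine ligands 12 were lower in alveolar cells, 4 higher and 4 not passed (16 when adjusted over the list alone); with the total count 16 were lower and 1, Ccl6, higher. Lower by less were Ccl9 (-1.13), Ccl17 (-1.10), Cxcl9 (-1.27), Cxcl16 (-1.27) and Ccl4 (-0.81). Cxcl3 was higher at 1.08, and Cxcl2 (0.53) and Cxcl14 (0.46) were higher but turned to -0.45 and -0.51 with the total count. Ccl3 at 0.58, Ccl22 at -0.10, Ccl5 at -0.45 and Cxcl10 at -0.72 did not pass, and with the total count the last 3 passed as lower, at -1.08, -1.42 and -1.69. Camera placed the ligands below other genes (adjusted p = 0.0131), which was lost at adjusted p = 0.0726 with an estimated correlation. Both tumor-promoting genes tested were lower (2 adjusted over the list alone), as were both antigen presentation genes (2 adjusted over the list alone) and the receptor gene Cxcr3 (-1.70, 1 adjusted over the list alone). Fabp5 was higher and Timd4 lower among scavenging genes (2 adjusted over the list alone). Of interferon-gamma-inducible genes Cxcl9 was lower, Irf1 was higher at 0.76 but lay at -0.22 with the total count, and Nos2 (0.36) and Cxcl10 did not pass (2 adjusted over the list alone); Il1b did not pass at 0.46.

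The median over the 56 genes was 0.13, and -0.85 with the total count, where 8 genes were higher and 32 lower, and -0.81 per cell, where 6 were higher and 28 lower. The count of higher genes therefore rests on TMM scaling, and Ccl17 lay at 0.13 with the marker gate.

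**Figure D3:**
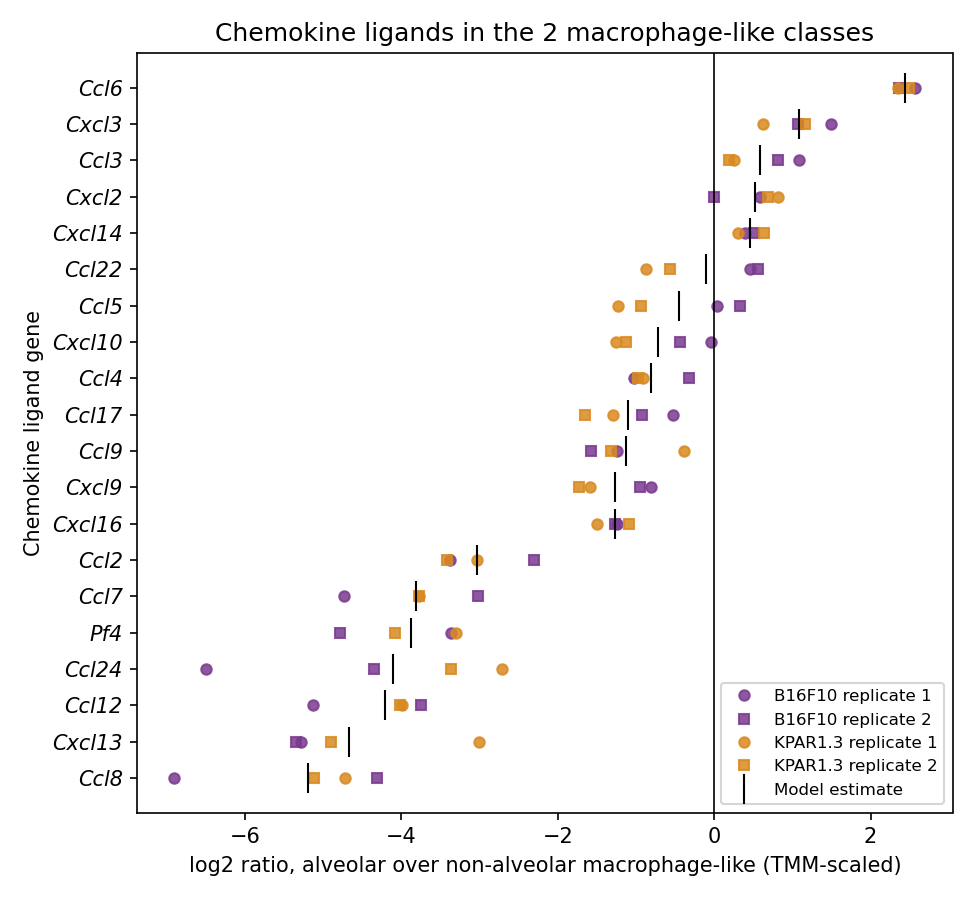
Log2 ratio of alveolar over non-alveolar macrophage-like cells for 20 chemokine ligands, scaled by TMM, with 1 point per mouse and a line for the model estimate. Ccl6 lay to the right in 4 of 4 mice, whereas Ccl8, Cxcl13, Ccl12, Ccl24, Pf4, Ccl7 and Ccl2 lay below -2 in each; with the total count, Ccl3, Cxcl2 and Cxcl14 turned negative.

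Whether this class contrast differed between models was tested gene by gene. Slc7a11 was far richer in alveolar than non-alveolar cells in B16F10, at 2.53 (log2, TMM scaling), but not in KPAR1.3, at 0.07, a difference of 2.46 ± 0.37 (SE). Clec4n differed by 1.61 ± 0.17, Osm by 1.45 ± 0.25 and Fabp5 by 1.15 ± 0.16, each with a larger ratio in B16F10. With TMM scaling all 3 were richer in alveolar cells of both models, whereas per cell Slc7a11 and Osm were lower in alveolar cells of both KPAR1.3 mice. The chemokines Ccl5 (0.19 and -1.08) and Ccl22 (0.50 and -0.71) took opposite signs in B16F10 and KPAR1.3 with TMM scaling, whereas per cell both were lower in alveolar cells of all 4 mice.

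Of 56 genes, 8 passed, 7 with a larger ratio in B16F10 and 1, C5ar1, with a smaller one (-0.80); each had an adjusted p of 0.0476. Bhlhe40 was the other gene, at 0.79, and with the marker gate Bhlhe40 and Fabp5 lay at -0.077 and -0.45. Of 20 ligands 2 passed and 18 did not, among them Cxcl9 at 0.78, Cxcl10 at 0.95, Ccl17 at 0.75, Ccl3 at 0.73, Ccl6 at 0.05 and Ccl24 at -2.28 (0 adjusted over the list alone; 0 of 20 passed edgeR there against 8 of 56 overall); camera gave adjusted p = 0.691. None of 4 interferon-gamma-inducible genes passed over all genes, with Irf1 at 0.74 and Nos2 at 0.10 (3 adjusted over the list alone). Fabp5 passed among scavenging genes and Timd4 did not at -2.18 (1 adjusted over the list alone), and H2-Aa (-0.09), H2-Ab1 (-0.19), Mmp12 (-0.52), Arg1 (-0.68), Cxcr3 (0.48) and Il1b (0.96) did not pass (0 in each list alone).

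This set of calls was fragile: edgeR called 0 of 56 genes with the total count (15 at an unadjusted p under 0.05), at Leiden resolution 2 (14), without the mouse term (11), without KPAR1.3 replicate 1 (7) and without KPAR1.3 replicate 2 (17). It called 2 per cell, 1 with the unnamed clusters put back, 4 with the marker gate, 5 without B16F10 replicate 1, 16 without B16F10 replicate 2 and 14 with clusters per model, and DESeq2 called 15.

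The last question was which cells held the transcripts of each chemokine ligand. Alveolar macrophage-like cells held 56.9% ± 1.85 of Ccl6 counts in B16F10 and 30.5% ± 8.24 in KPAR1.3 (SD, n = 2 each), 6.40 and 5.11 times their share of all shared-gene counts. Non-alveolar macrophage-like cells held 41.0% ± 1.26 and 46.4% ± 0.95 of Ccl9 and 34.0% ± 5.77 and 20.5% ± 4.83 of Cxcl13. Dendritic cell-like cells held 43.7% ± 0.365 and 42.1% ± 2.82 of Ccl17, a chemokine that attracts T cells through Ccr4. The T cell attractants Cxcl10 and Ccl5 and the ligand Cxcl14 had 91.1%, 90.4% and 91.1% of counts outside the 3 classes in B16F10 and 71.1%, 79.7% and 79.8% in KPAR1.3, against 83.1% and 70.5% of all shared-gene counts. These shares moved with the class definition: in 6 other settings, 32 of 60 B16F10 values over the 10 ligands moved by more than 1 SD in each macrophage class, as did 16 of 60 KPAR1.3 values in alveolar and 18 in non-alveolar cells.

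For comparison, all shared genes placed 8.90% and 5.96% of counts in alveolar, 5.31% and 16.2% in non-alveolar and 2.72% and 7.35% in dendritic cell-like cells of B16F10 and KPAR1.3. Non-alveolar cells held 10.8% and 23.1% of Cxcl9, 8.19% and 22.5% of Cxcl16 and 12.4% and 29.3% of Ccl6 in B16F10 and KPAR1.3. Dendritic cell-like cells held 14.9% and 13.8% of Ccl22. The median over the 10 ligands was taken per mouse and then averaged over the mice of a model. In non-alveolar cells it was 6.74% in B16F10 and 18.6% in KPAR1.3, and the marker gate moved it to 21.0% and 24.6%. In alveolar cells the medians were 3.53% and 1.65%, and 8.22% and 3.91% with the gate; no test was run on these shares, and putting the unnamed clusters back moved the B16F10 non-alveolar value to 13.4%.

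**Figure D4:**
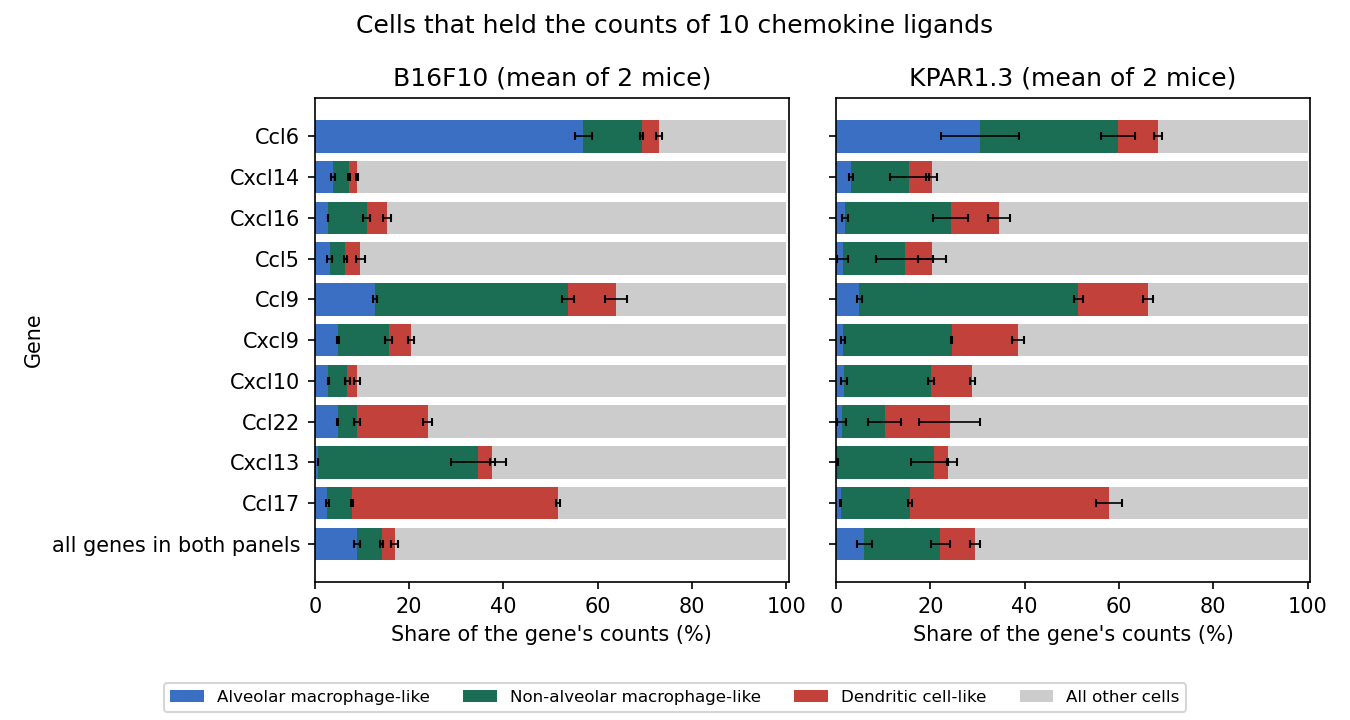
Share of each ligand's counts (%) held by 3 classes and by all other cells, as stacked bars of the mean of 2 mice per tumor model with SD bars at each class boundary; the lowest bar gives all genes in both panels. Alveolar cells held 56.9% of Ccl6 in B16F10 but 30.5% in KPAR1.3, where non-alveolar cells held 29.3% and other cells 31.8%. Non-alveolar cells held 41.0% and 46.4% of Ccl9 and dendritic cell-like cells 43.7% and 42.1% of Ccl17.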

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

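All tests weighed below were chosen after the results they concern had been seen.

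The class contrast (alveolar over non-alveolar macrophage-like cells, log2) differed between models, by the class-by-model test, for 8 genes. The difference, B16F10 minus KPAR1.3, was 2.46 for Slc7a11, 1.61 for Clec4n, 1.45 for Osm, 1.27 for Ccl5, 1.22 for Ccl22, 1.15 for Fabp5, 0.79 for Bhlhe40 and -0.80 for C5ar1. Signal also appeared in data the comparisons did not use: 201 of the 204 genes only in the B16F10 panel and all 4 genes only in the KPAR1.3 panel exceeded the highest negative control probe in both of their sections. In both B16F10 sections 1 unassigned codeword exceeded that probe; the highest codewords drew 1520 and 940 counts and the highest probes 574 and 932.

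Irf1 was lower in B16F10 in whole sections and in both macrophage-like classes, by log2 fold changes of -3.11, -3.71 and -3.05. It was lower in 100% of the 49 clusters with at least 500 cells in every section, with a median log2 ratio of -2.76 ± 0.42 relative to the median gene (SD over clusters), the value needed if the Irf1 probes work less well in the B16F10 panel, although both panels list 8 probe sets for it. Cxcl9, Cxcl10 and Nos2 were all lower in 75.5% of the same clusters, which a weaker interferon-gamma response in B16F10 lungs also needs. Of the other 95 genes, 6 also kept 1 direction in all 49 clusters (Bhlhe40, Ctsd, Ifit1, Igf1 and Pf4 higher and Clec4n lower in B16F10), and Isg15, like Ifit1 induced by interferons, was higher in 48. Both explanations stay open and could act together, because every B16F10 section used the 300-gene panel and every KPAR1.3 section the 100-gene panel.

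In non-alveolar macrophage-like cells 22 genes were higher and 24 lower in B16F10. Melanoma transcripts assigned to these cells are argued against as the whole cause: Pmel per cell was 3.45% and 1.08% of that in the melanoma-rich cluster, in part because clusters with Pmel over 25% of the highest had lost their name, and transcripts at that rate gave the larger part of the excess for 0 of the 22 higher genes, and their dilution gave 3.78% of the median fall of the 24 lower genes. Panel efficiency cannot be told apart from tumor model: of the 25 genes held out of clustering that passed, 3 had a class contrast that differed between models, and a probe that works less well in all cells would leave that contrast unchanged, so the other 22 stay open. Of the 3, Clec4n differed by 1.61 ± 0.17 (SE) and by at least 1.33 under every alternative, although its call was lost under some, which argues against panel efficiency as its whole cause; Slc7a11 fell to 0.33 with the marker gate and Ccl22 to 0.13 with clusters per model, so both stay open. A biological difference between melanoma and adenocarcinoma lungs, a changed mixture of cells in the class included, also stays open.

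Alveolar and non-alveolar macrophage-like cells differed in 46 of 56 held-out genes. Of the 8 splits of the 8 class sums that part every mouse, 1, the real one, gave as many, with at most 0 elsewhere (no gene passed edgeR's adjusted threshold there), and so few splits cannot give a share under 0.05; over all 35 splits without the mouse term the real one called 40 genes and the highest other 1 (2.86% as large), but those splits ignore that both classes come from the same mice. Of the 23 genes higher in alveolar cells, 13 stayed higher with the total count in place of TMM. How many are truly richer there therefore cannot be told apart from the scaling. All 23 lower genes were lower with the total count too. That was fixed in advance, since this scaling lowered the ratios, such as Ccl6 from 2.45 to 1.47 and Ccl8 from -5.20 to -6.16. Transcripts of neighbouring cells may add to the higher genes, since 75% of 4 epithelial and endothelial markers only in the B16F10 panel (Sftpd, Ager and Flt1, not Vwf) had more counts per alveolar cell in both mice. A true difference between the classes, which were defined by other genes, stays open as well.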

How the results depend on the processing

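Putting the unnamed clusters back, and the marker gate for sources, were chosen after the data had been examined; the other settings were chosen before. The cause was not tested for any change listed here. The class contrast called 34 to 51 of 56 genes under all 15 settings, and Irf1 stayed lower in B16F10 in every setting of the 3 model comparisons. The minimum of 5 or 20 transcripts per cell moved no call count or share past its threshold, and omitting the low-count filter removed no gene, so it tests nothing. With each mouse left out, which leaves 1 mouse in an arm and assumes that it varies like the others, edgeR called 12 to 51 genes in whole sections, 0 to 45 in non-alveolar, 0 to 43 in alveolar cells, 43 to 45 between classes and 0 to 16 for the class-by-model term. The share ranges were 0.20 to 0.61 for alveolar, -1.66 to -1.34 for non-alveolar and -1.65 to -1.17 for dendritic cell-like cells (log2), and those of the ligand medians 6.38% to 7.10% and 17.6% to 19.5% for non-alveolar and 3.24% to 3.83% and 1.15% to 2.15% for alveolar cells of B16F10 and KPAR1.3. The class-by-model term called 0 genes with the total count, at Leiden resolution 2 and without the mouse term (15, 14 and 11 at an unadjusted p under 0.05), 2 with the offset by number of cells, 15 with DESeq2, 14 with clusters made per model, 4 with the marker gate and 1 with the unnamed clusters put back. The marker gate gave 30 genes in non-alveolar cells, a non-alveolar share difference of -0.42 and ligand medians of 21.0% and 24.6% (non-alveolar) and 8.22% and 3.91% (alveolar). Clusters per model gave non-alveolar medians of 8.30% and 16.4%, resolution 2 gave 15.8% for KPAR1.3 and alveolar medians of 1.43% and 0.828%, and the unnamed clusters gave 13.4% for B16F10. Among immune-named cells, which are the 3 classes alone, the alveolar share passed at 1.20. By the exact permutation test the non-alveolar (-1.51) and dendritic (-1.39) shares did not pass. Signs turned per cell between models for Ccl9 (-0.20), H2-Aa (-0.56) and Fn1 (-0.44) in non-alveolar and Chil3 (-0.17) in alveolar cells, and between classes for Cxcl14 (-0.48), Cxcl2 (-0.41) and Irf1 (-0.18); with the total count the class contrast turned, among named genes that passed in either fit, for Cxcl14 (-0.51), Cxcl2 (-0.45), Irf1 (-0.22) and Nos2 (-0.61). The marker gate turned Slc7a11 (0.31), Ccl9 (-0.067), H2-Aa (-0.43), Fabp5 (1.01), Timd4 (-0.27) and Fn1 (-0.029) in non-alveolar cells, Ccl17 (0.13) between classes, and Fabp5 (-0.45) and Bhlhe40 (-0.077) in the class-by-model term. The unnamed clusters turned H2-Aa (-0.10) and Fabp5 (1.06) in non-alveolar cells and Fabp5 (-0.016) in the class-by-model term, and clusters per model, which put a cluster led by Fabp4 into the B16F10 alveolar class, turned Napsa (-0.92), Apoe (0.18), Ccl5 (-0.98) and Cxcl13 (2.47) in alveolar cells. With the replicate number as a block, 38, 54 and 39 genes passed in whole sections, non-alveolar and alveolar cells; log2 deviations of mice with the same number correlated at 0.154, 0.414 and 0.200 over 96 genes, which are not independent replicates, and the numbers do not pair mice between models. Depth limits little here, except for genes near the control probes, such as Ccl8, Timd4 and Ccl24 in alveolar cells. By contrast, 2 mice per model limit what folds under 2 can show.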

Other observations

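The genes only in the B16F10 panel, which no comparison used, were set beside the classes of the 2 B16F10 mice without a test, and the genes named here were chosen after their values were seen. Of 4 alveolar markers there, 3 had more counts per alveolar cell: log2 ratios per cell of alveolar over non-alveolar cells were 2.46 ± 0.0031 for Pparg (SD, n = 2), 1.79 ± 0.694 for the scavenger receptor gene Marco and 1.51 ± 0.033 for the lipase gene Lpl. Fabp4, the fourth, went the other way at -1.40 ± 0.676. Counts per cell were higher in non-alveolar cells for the complement gene C1qa (-6.82 ± 0.356), the integrin gene Itgam (-4.63 ± 0.0467), the lectin gene Clec10a (-6.32 ± 0.619), the growth factor receptor gene Csf1r (-1.87 ± 0.135) and the costimulatory gene Cd86 (-3.42 ± 0.425). None of these genes took part in the joint clustering that made the classes. The cell type markers among them did take part where clusters were made per model.

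Some other genes had more counts per alveolar cell: the log2 ratio was 2.28 ± 0.349 for Cd274, which encodes PD-L1, 2.21 ± 0.313 for Il1a and 1.00 ± 0.0288 for Tnf (SD, n = 2). Vegfa lay at 0.93 ± 0.0684 and Gpnmb, which melanoma cells also express, at 0.97 ± 0.443. With clusters made per model, Vegfa was among the leading genes of a B16F10 cluster led by Pdpn and Ager. Il1a was among those of a B16F10 cluster with Car4 and Pecam1. Whether neighbouring cells added to the counts of Vegfa and Il1a was not tested. Il10 lay at -2.45 ± 1.13, and Il6 at -1.41 ± 0.923. Markers of other cells also had more counts per alveolar cell, with Flt1 at 1.61 ± 0.188 and Ager at 0.98 ± 0.192. In the KPAR1.3 sections the alveolar marker Krt79, absent from the other panel, was counted 1.25 and 1.503 times per alveolar cell and 0.0209 and 0.0213 times per non-alveolar cell.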
